A study of Homo sapiens with 4 samples.

How the data were processed

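RNA of OCI-Ly10 cells was compared on 4 arrays with 2 channels each. Per the labels, cells were electroporated with a siRNA pool against MYC at 4 uM or treated as controls. Total RNA was extracted with Trizol, and 50 ug was reverse transcribed from oligo dT and labelled. The RNA of cells with MYC siRNA carried Cy5 and the control RNA Cy3 on each array, per the labels, and 0 arrays had the dyes swapped. On 2 arrays the control cells had been given a nonspecific siRNA against Renilla luciferase (8 h and 24 h), and on the other 2 they had been electroporated in buffer without siRNA (6 h and 24 h).

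The values analysed were the authors' processed log2 ratios, 1 per feature and array, as deposited in the value table of the series. Log base, direction, background correction, normalization and the reason for empty cells are not given in the sources used here. The values were signed, centred near 0 and reached 6.63, which was taken as a log2 scale. The direction was taken as Cy5 over Cy3, so that negative values mean less transcript with MYC siRNA. This direction is likely rather than stated: the dyes come from the labels, and MYC itself lay below 0 in 13 of its 14 values. Scanner intensities were not used here, so the signal over background of single features is unknown.

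The table held 15154 features. Of these, 10161 had a value on all 4 arrays, 4090 on some and 903 on none. Gene symbols came from the platform annotation given for this series and were updated by Entrez ID through a RefSeq table of assembly GRCh38.p14, used for names alone. A match was found for 10124 features. One symbol was listed for 10165 features, several for 4 and none for 4985. Features with several symbols were not named. Features that shared 1 symbol were averaged on each array, over those with a value there, and features without a symbol stayed separate. This gave 6798 rows with a value on all 4 arrays, of which 3954 were named genes and 2844 single features. No coordinates are given, since the sources name no genome build.

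Before the data were examined, the tests, 27 gene lists, the rule for named genes and all but 1 of the alternatives were fixed. The mean log2 ratio of each row over the 4 arrays was tested against 0 with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3), with 3 residual degrees of freedom per row before moderation. Differences between 24 h and the earlier arrays, and between the 2 kinds of control, were tested with limma as 2 terms of 1 model, which left 1 residual degree of freedom. The 6 h and 8 h arrays formed the early class. P-values were adjusted by Benjamini-Hochberg over all rows, with a threshold of 0.05. For MYC, an exact sign-flip permutation test over the 16 sign patterns was added, whose smallest two-sided p is 0.125.

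Gene lists with at least 5 measured members, 26 of the 27, were tested with camera from limma at a preset correlation of 0.01, with an estimated correlation, and with fry. Adjustment was over the lists. Members were counted by the test over all rows and by the p-values adjusted over the list alone. List tests for time and control kind were added after the data were examined. The share of random lists was taken over 10000 draws of the same size.

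Named genes were MYC, the 12 lowest and 12 highest genes among those past the threshold with 1 sign on all arrays, the 5 largest each way for the other comparisons, up to 4 members per list in the direction of its median, and members of the MYC network list. Where fewer than 5 passed, genes with an unadjusted p under 0.05 filled the places. Other members of lists with few calls are named so that small counts can be read, and these were chosen after their values were seen.

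The arrays carry replicate numbers in order of listing only, so no pairing was fitted. Each combination of control and time was measured on 1 array. The labels do not say whether cultures were separate beyond each array, so p-values measure the spread between these 4 arrays, part of which may be technical. Limma draws a row's spread toward that pooled over all rows. Prior degrees of freedom were 17.5 against 1 residual for time and control kind, and 6.31 against 3 for MYC siRNA. Standard errors and p-values by time and control kind thus rest mostly on the pooled spread, not on that of the gene. The kind of control also goes with the experiment, as the array identifiers fall into 2 ranges. Batch and control kind cannot be told apart. The number of arrays limits the precision: the median standard error of the mean log2 ratio was 0.0951.

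The code was tested on simulated values with the rows of the real table and 200 changed rows, 100 at each size. Their spread was that of the fit with time and control as terms (17.5 prior degrees of freedom). The MYC siRNA fit had 6.31, and its spread also holds time and control differences. The simulated shares for that comparison therefore do not give the recovery or false calls of the real test. For the MYC siRNA comparison over 6798 rows, 93% of rows changed by 0.5 and 100% of those changed by 1 were recovered, with 13 false calls among 206. For late against early the shares were 14% and 94%, with 11 false calls among 119. For the kind of control they were 16% and 95%, with 11 among 122. A simulated shift of 1 list was recovered by camera, and 0 of 15 lists without shifted members passed. Since simulated rows were drawn independently, this cannot show how often camera calls lists of correlated genes. In the real values the estimated correlation was 0.482 for translation factors and 0.358 for NF-kappaB targets, but 0.044 for ribosome biogenesis and 0 for MYC-repressed genes. With an estimated correlation, camera's test has the residual degrees of freedom of the fit, 3 or, for time and control kind, 1. The MYC-repressed list still went from a camera adjusted p of 0.00631 to 0.528. A call lost in this setting therefore does not show that correlation between genes made it.

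Alternatives changed the centring and scale of the arrays, the arrays used, the rows tested, the threshold, a filter on small values, the spread estimate and the terms of the model. The one added after the data were examined averaged only features with a value on all 4 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.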

Results

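Transcript levels after knockdown of MYC, a transcription factor that drives growth and proliferation in many lymphomas, were measured in OCI-Ly10 cells. OCI-Ly10 is an established human line of diffuse large B-cell lymphoma of the activated B-cell type. The series asks which genes respond to a siRNA pool against MYC. RNA of cells given 4 uM of the pool was hybridised together with control RNA on 4 arrays. Controls were cells with a nonspecific siRNA (8 h and 24 h) or cells electroporated in buffer without siRNA (6 h and 24 h), with 1 array per combination. Values were present for 12784 and 12697 features on the arrays against control siRNA and for 12076 and 12028 on those against no siRNA, early array first. The median log2 ratios were 0.008, 0.014, -0.008 and -0.034, and the standard deviations over features 0.327, 0.324, 0.288 and 0.447, in the same order. Log base 2 and a direction of MYC siRNA over control were taken from the values and the dyes, since the sources used here do not state them.

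Under the direction taken, MYC transcript was lower in cells with the MYC siRNA on each of the 4 arrays. The sign of the MYC values helped set that direction, so it is not separate evidence of knockdown. The mean log2 ratio was -0.89 ± 0.39 (SD, n = 4), which is 53.8% of control, with an adjusted p of 0.0146 in limma. By array it was -0.94 at 8 h and -0.35 at 24 h against control siRNA, and -1.26 at 6 h and -1.03 at 24 h against no siRNA. These values correspond to 52.1%, 78.6%, 41.9% and 48.8% of control. The gene was measured by 4 features, and 13 of their 14 values were below 0. The exception was a value of 0.11 on the 24 h array against control siRNA. The exact sign-flip test gave a two-sided p of 0.13 (2 of 16 sign patterns), the smallest that 4 arrays allow. Without the 6 h array the mean was -0.77, and limma's adjusted p rose to 0.053.

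NOP56, HSPA9 and FKBP4, of the lists for ribosome biogenesis, mitochondrial biogenesis and cytosolic chaperones, stood among the 12 named genes that fell most with MYC siRNA. CYP2B6, a cytochrome P450, had the lowest mean of the named genes, -1.11 ± 0.38 (SD, n = 4). CYCS, which encodes cytochrome c, fell by 0.92 (SD 0.41, n = 4) and NOP56, a core protein of box C/D snoRNPs, by 0.88 (SD 0.55, n = 4). HSPA9, the mitochondrial Hsp70 chaperone, averaged -0.79 ± 0.61, SLC25A33, a mitochondrial carrier of pyrimidine nucleotides, -0.78 ± 0.18, and FKBP4, a cochaperone of Hsp90, -0.78 ± 0.48 (SD, n = 4 each). DHX15, an RNA helicase of the splicing machinery, and THOC1, of the mRNA export complex THO, both averaged -0.78, with SDs of 0.63 and 0.47. The other genes at the low end were COCH (-0.88 ± 0.28), the histone acetyltransferase gene KAT6B (-0.86 ± 0.23) and the small GTPase gene ARF3 (-0.85 ± 0.40). Adjusted p in limma lay between 0.00946 (CYP2B6, KAT6B and SLC25A33) and 0.0312 (DHX15) for these genes. CYCS and NOP56 had 2 features each, while the others named in this paragraph rested on 1 feature each, without a dye swap. Without the 24 h array against no siRNA, HSPA9 averaged -0.51 and did not pass (limma adjusted p = 0.0528).

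Among named genes past the test with 1 sign on all 4 arrays, LGALS1, which encodes galectin-1, a galactoside-binding lectin, had the highest mean, 0.87 ± 0.64 (SD, n = 4; limma adjusted p = 0.0253). GIT2 (1.22 ± 2.28) and WASH5P (0.89 ± 2.18) had higher means, each from 1 array, and did not pass, nor did the feature 25108_1, without a symbol, at 0.91. The values of LGALS1 were 0.33 and 0.31 on the early arrays and 1.48 and 1.36 at 24 h. The receptor tyrosine phosphatase genes PTPRF (0.65 ± 0.13) and PTPRO (0.61 ± 0.31) rose, as did CD1C (0.64 ± 0.29), which presents lipid antigens. MACF1 was at 0.60 ± 0.34, KATNAL1 at 0.60 ± 0.22 and CALD1 at 0.57 ± 0.26. The nuclear pore gene POM121 rose by 0.60 (SD 0.30), the helicase gene DHX36 by 0.57 (SD 0.31) and RPAP2, a phosphatase of RNA polymerase II, by 0.64 (SD 0.52). ABTB1 (0.60 ± 0.35) and SERTAD2 (0.57 ± 0.47) completed the 12 highest. Of these, RPAP2, MACF1, POM121 and DHX36 rested on 1 feature each and the others on several. Adjusted p in limma reached 0.0396 (SERTAD2), which averaged 0.36 and did not pass without the 24 h array against no siRNA (adjusted p = 0.0877).

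**Figure D1:**
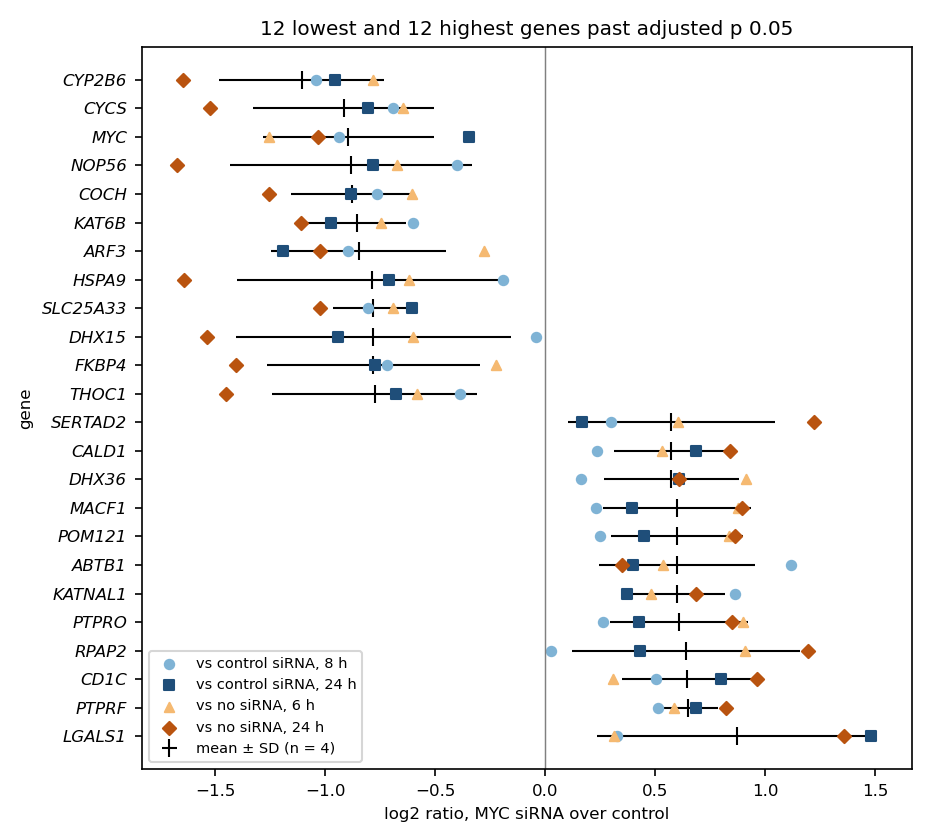
Log2 ratio of MYC siRNA over control (x axis) for the 12 lowest and 12 highest named genes past the test (y axis), with 1 symbol per array and a black tick and bar for the mean ± SD over the 4 arrays. MYC values run from -1.26 to -0.35, and the 24 h array without control siRNA holds the lowest value of NOP56 (-1.68) and HSPA9 (-1.64).

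In all, 1073 of 6798 rows changed, 695 lower and 378 higher (limma, adjusted p under 0.05). Lower rows made up 64.8% of these under the direction taken, and would be the higher ones if the ratios run the other way. With time and control as terms, 56.8% of 1980 changed rows were lower. Named genes made up 384 of the lower and 203 of the higher rows. An unadjusted p under 0.05 was found for 2405 rows, against 340 given by chance. With 0 dye swaps, a dye bias of single genes would add to these counts as a response would. The count fell with any array left out, when fewer residual degrees of freedom remain. It was 441 without the 8 h array and 4 without the 24 h array against control siRNA. Against no siRNA it was 0 without the 6 h array and 234 without the 24 h array. Rows at an unadjusted p under 0.05 in limma were then 2004, 1895, 2179 and 1796, in that order. The fall in the count thus does not show that the changes came from single arrays. With the count at 0 the smallest adjusted p in limma was 0.053, and of the 4 rows, 1 was MYC and 3 were features without a symbol.

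Across the 6798 rows, each pair of arrays correlated positively. Pearson's r ran from 0.354 to 0.582 with a median of 0.457, and was highest between the 2 arrays at 24 h. These are correlations across genes, which are not independent replicates. MYC siRNA carried Cy5 on each array, so a dye bias of single genes would also give positive correlations. The 2 cannot be told apart here. Over 1837 genes measured by several features, the means of 2 features correlated at r = 0.346, against -0.0011 for randomly paired features, and 34 genes had features called in both directions, BCL2 and ATM among them (named after their values were seen).

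Growth and biosynthesis genes made up the lists that shifted down. Of 15 measured genes of ribosome biogenesis, 7 fell, 0 rose and 8 did not pass (8 fell when adjusted over the list alone), with a median log2 ratio of -0.33. NPM1, the nucleolar chaperone nucleophosmin, averaged -0.63 ± 0.30, NOLC1 -0.56 ± 0.13 and the helicase gene DDX21 -0.53 ± 0.13 (SD, n = 4 each). Among 20 translation factors 9 fell, 0 rose and 11 did not pass (10 fell adjusted over the list alone; median -0.24). EIF1AX, of the initiation machinery, averaged -0.68 ± 0.24, GSPT1, the release factor eRF3a, -0.63 ± 0.25 and EIF3B -0.49 ± 0.20. Of 8 aminoacyl-tRNA synthetase genes, IARS1 (-0.48 ± 0.17) and EPRS1 (-0.39 ± 0.14) fell and 6 did not pass (4 fell adjusted over the list alone; median -0.30), with TARS1 at -0.38 and GARS1 at -0.30. Left-out arrays moved TARS1 from -0.457 to -0.232. Limma's camera gave adjusted p values of 0.00299, 0.000419 and 0.0277 for these 3 lists, and adjusted p = 0.528 for each with an estimated correlation. The synthetase call was lost without the 24 h array against control siRNA (median -0.22, adjusted p = 0.119), and the median was -0.18 without that against no siRNA (adjusted p = 0.0494). With fry, translation factors and synthetases did not pass (adjusted p = 0.0886 each).

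Nucleotide and one-carbon synthesis had a median of -0.22, with 6 of 24 genes lower, 0 higher and 18 not passing (7 lower adjusted over the list alone). UCK2, which salvages uridine and cytidine, averaged -0.67 ± 0.16 and the purine synthesis genes GMPS and PAICS -0.63 ± 0.31 and -0.53 ± 0.30 (SD, n = 4), while IMPDH2 at -0.41 did not pass. In mitochondrial biogenesis 5 of 15 genes fell, 0 rose and 10 did not pass (adjusted over the list alone, 5 fell and 1 rose; median -0.24): HSPA9, TFAM, the packaging factor of mitochondrial DNA (-0.75 ± 0.37), MRPL19 (-0.77 ± 0.23), TOMM20 (-0.42 ± 0.17) and TIMM44 (-0.34 ± 0.19). Cytosolic chaperones had a median of -0.34, close to that of ribosome biogenesis (-0.33), with 5 of 10 lower, 0 higher and 5 not passing (8 lower adjusted over the list alone). These were FKBP4, DNAJC2 (-0.65 ± 0.16), CCT3 (-0.39 ± 0.17) and the Hsp90 genes HSP90AA1 (-0.48 ± 0.24) and HSP90AB1 (-0.38 ± 0.20). In glycolysis HK2 (-0.60 ± 0.05) and LDHA (-0.46 ± 0.12) fell and 14 of 16 genes did not pass (2 fell adjusted over the list alone; median -0.13). Camera's adjusted p was 0.000419, 0.00275, 0.000842 and 0.0414 for these 4 lists in limma, and adjusted p = 0.528 for each with an estimated correlation. The glycolysis call was lost without either 24 h array (median -0.11, adjusted p = 0.166 without that against control siRNA, and median -0.07, adjusted p = 0.127 without that against no siRNA), with scaled arrays (-0.10, adjusted p = 0.0674) and with fry (adjusted p = 0.0886).

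The list of textbook MYC-activated genes had a median of -0.26, with 11 of 26 genes lower, 0 higher and 15 not passing (12 lower and 1 higher adjusted over the list alone). It shares 20 of its 26 measured genes with other lists. TERT, the catalytic subunit of telomerase, averaged -0.60 ± 0.24 (SD, n = 4), and FKBP4, TFAM and NPM1 were its other lowest members. Camera gave an adjusted p of 9.18e-05 in limma, and adjusted p = 0.528 with an estimated correlation (0.0877 with fry). Partners and relatives of MYC itself did not pass as a list (median -0.002, and 0.009 with centred and 0.011 with scaled arrays; adjusted p = 0.785): MAX was at -0.20, MXD3 at 0.26, RUVBL1 at -0.35, RUVBL2 at -0.12, BIN1 at 0.34, MXD1 at 0.10, TRRAP at 0.07, MYCL at 0.01 and MYCN at -0.02, and MYC was the 1 of 10 to pass (adjusted over the list alone, 2 fell and 1 rose).

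**Figure D2:**
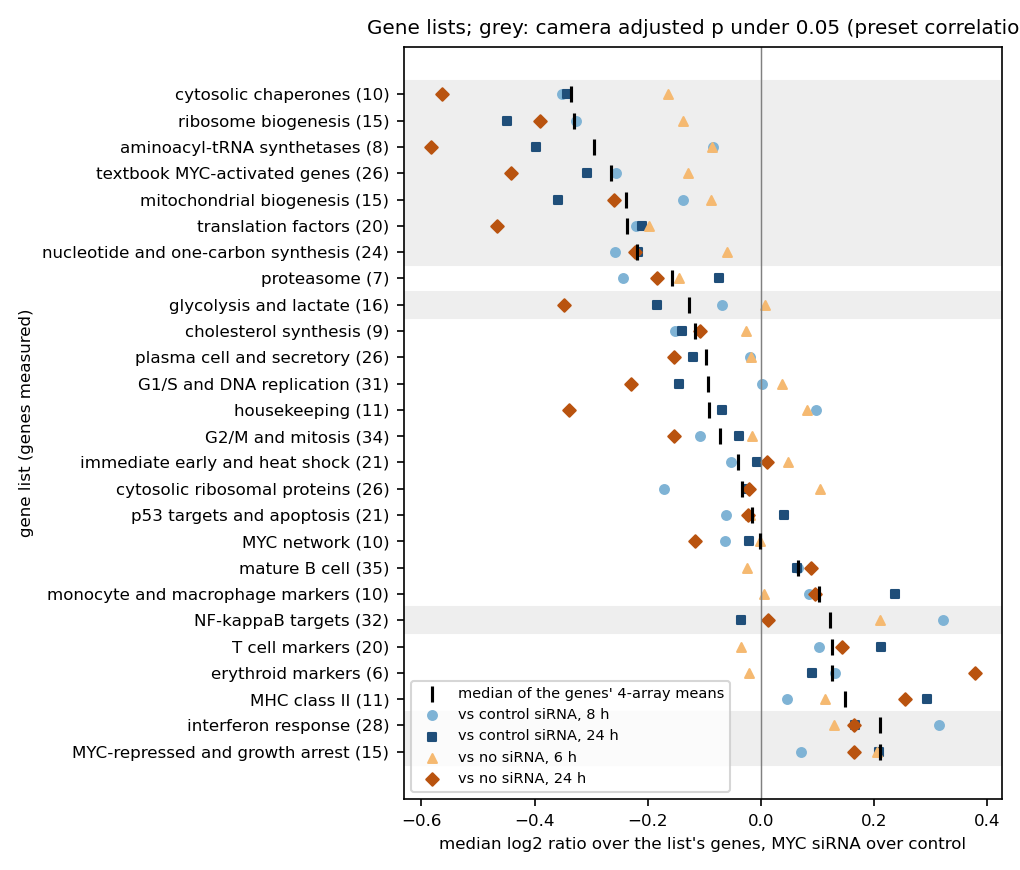
Median log2 ratio of MYC siRNA over control over the measured genes of each list (x axis), with the number of genes in brackets, 1 symbol per array and a black tick for the median of the genes' 4-array means. Grey bands mark 11 lists with a camera adjusted p under 0.05 at the preset correlation, 8 lower and 3 higher. With an estimated correlation 0 kept it. That setting has 3 residual degrees of freedom, and the MYC-repressed list lost its call there with an estimated correlation of 0.

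The list of ribosomal protein genes did not pass. Of 26 measured, RPL11 fell (-0.45 ± 0.06) and 25 did not pass (1 fell adjusted over the list alone), with a median of -0.03, RPL5 at -0.21, RPL13 at -0.16 and RPS2 at -0.13 (camera adjusted p = 0.785, limma). The proteasome list had a median of -0.16 with PSMB4 lower (-0.40 ± 0.21) and 6 of 7 not passing (adjusted over the list alone, 1 fell and 1 rose), among them PSMA7 (-0.26), PSMB7 (-0.19) and PSMD14 (-0.16). Among 31 genes of G1/S and DNA replication, POLA1 (-0.53 ± 0.16) and CDK4 (-0.44 ± 0.29) fell and 29 did not pass, with CDC6 at -0.37 and POLD2 at -0.29 (median -0.09; 1 fell adjusted over the list alone). Of 34 mitotic genes, NEK2 (-0.59 ± 0.26), TPX2 (-0.39 ± 0.23), BUB1B (-0.34 ± 0.08) and CCNB2 (-0.30 ± 0.07) fell (4 adjusted over the list alone; median -0.07), while TTK at -0.35 did not pass. Camera gave adjusted p values of 0.168, 0.139 and 0.139 in limma for the proteasome, G1/S and mitotic lists. The G1/S list passed camera without the 6 h array (median -0.125, adjusted p = 0.0375). With either 24 h array left out its median was -0.051. The mitotic median was -0.014 without the 24 h array against no siRNA.

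The 3 lists that shifted up held growth-arrest, interferon response and NF-kappaB genes. In the list of MYC-repressed and growth-arrest genes 4 of 15 rose, 0 fell and 11 did not pass (5 rose adjusted over the list alone; median 0.21). These were NDRG1 (0.47 ± 0.30), KLF4 (0.43 ± 0.15), CDKN2D, an inhibitor of CDK4 and CDK6 (0.39 ± 0.26), and TSC22D3 (0.33 ± 0.13; SD, n = 4 each), while BIN1 at 0.34 did not pass. Of 28 interferon response genes 10 rose, 0 fell and 18 did not pass (11 rose adjusted over the list alone; median 0.21). IFI6 averaged 0.51 ± 0.32, IFIT1 0.45 ± 0.03, ISG15 0.43 ± 0.24 and MX1 0.42 ± 0.16. Of 32 NF-kappaB targets, 6 rose, 0 fell and 26 did not pass (6 adjusted over the list alone; median 0.12), with CD44 at 0.46 ± 0.12, EBI3 at 0.43 ± 0.13, PTPN1 at 0.40 ± 0.11 and BCL2A1 at 0.34 ± 0.21. Camera's adjusted p was 0.00631, 0.000419 and 0.00631 for these lists in limma, and adjusted p = 0.528 for each with an estimated correlation. The NF-kappaB call was lost without the 8 h array (median 0.06, adjusted p = 0.156) and with fry (adjusted p = 0.211). Markers of other lineages also lay above 0 in the mean over arrays, with medians of 0.12 for T cell, 0.10 for monocyte and 0.13 for erythroid genes. Without the 24 h array against no siRNA these medians were 0.08, 0.12 and 0.06. On the 6 h array by itself they were -0.035, 0.006 and -0.021. T cell markers passed camera without the 6 h array (median 0.11, adjusted p = 0.0375). Rows with empty cells on some arrays had a median of 0.07 against -0.003 for complete rows.

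The 3 lists of B-cell identity did not pass camera. MHC class II had a median of 0.15 with CD74, the invariant chain (0.37 ± 0.07), and HLA-DOB (0.50 ± 0.38) higher and 9 of 11 not passing (2 rose adjusted over the list alone), among them HLA-DMB (0.26) and HLA-DRB1 (0.23). Of 35 mature B-cell genes CD72 (0.41 ± 0.32) and CD79A, a signalling chain of the B-cell receptor (0.41 ± 0.27), rose and 33 did not pass, with CD52 at 0.29 and SPIB at 0.26 (median 0.07; 0 rose adjusted over the list alone). CD72 averaged 0.26 and did not pass without the 24 h array against no siRNA (limma adjusted p = 0.124). Among 26 plasma cell and secretory genes LMAN1 (-0.57 ± 0.35), CANX (-0.48 ± 0.32) and SPCS3 (-0.33 ± 0.12) fell and SLAMF7 rose (0.39 ± 0.22), and the median was -0.10 (adjusted over the list alone, 3 fell and 1 rose). This median was -0.046 without the 24 h array against control siRNA and -0.059 without that against no siRNA. Without the 8 h array it was -0.125, and without the 6 h array -0.094. HSP90B1, the Hsp90 chaperone of the endoplasmic reticulum, averaged -0.65 and did not pass, with 0.23 on the 8 h array and -1.66 on the 24 h array against no siRNA. It averaged -0.94 without the former and -0.31 without the latter. Camera's adjusted p in limma was 0.0537, 0.139 and 0.304 for these lists, and adjusted p = 0.528 for each with an estimated correlation. MHC class II passed without the 8 h array (median 0.24, adjusted p = 0.0167), over single features (0.26, adjusted p = 8.91e-06) and over features complete on all arrays (0.19, adjusted p = 0.0316), and the mature B-cell list over single features (0.06, adjusted p = 0.0242). Over single features each feature counts as a member, and CD74 has 12 and HLA-DMB and HLA-DRB1 7 each. Features of 1 gene are not independent, so those adjusted p values overstate the support by gene.

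Stress and metabolic control lists did not pass either. In the p53 list of 21 genes (median -0.02, adjusted p = 0.94) BIK (0.33 ± 0.17) and GDF15 (0.31 ± 0.13) rose, but 0 did when adjusted over the list alone. PMAIP1 at -0.28, BCL2L1 at -0.24, RRM2B at -0.19 and PPM1D at -0.16 did not pass. Of the immediate early and heat shock genes NR4A1 fell (-0.65 ± 0.41) and JUN rose (0.32 ± 0.13), with FOS at -0.27, DUSP2 at -0.27 and TRIB3 at -0.27 (21 measured, median -0.04, adjusted p = 0.84; adjusted over the list alone, 1 fell and 0 rose). In cholesterol synthesis FDPS fell (-0.46 ± 0.19) and SREBF2, which encodes the transcription factor of the pathway, rose (0.34 ± 0.09), with INSIG1 at -0.19, SQLE at -0.16 and IDI1 at -0.13 (9 measured, median -0.12, adjusted p = 0.279; adjusted over the list alone, 1 fell and 1 rose). The housekeeping list had a median of -0.09 (adjusted p = 0.785), with B2M higher (0.32 ± 0.18) and HPRT1 at -0.30, PGK1 at -0.27, TUBB at -0.16 and TBP at -0.12 (11 measured, 0 changed adjusted over the list alone). SAT1, which acetylates spermidine and spermine for their breakdown, rose by 0.50 (SD 0.38, n = 4) in the polyamine list, too small to test. Of the lineage markers, CSF3R (0.30 ± 0.11; 1 of 10 monocyte genes) and GATA1 (0.48 ± 0.19; 1 of 6 erythroid genes) rose, and 0 of 20 T cell genes passed in limma. Adjusted over the list alone, GATA1 passed and 0 monocyte or T cell genes did. CD4 (0.33), GZMK (0.29), LCK (0.28), GZMA (0.25), TYROBP (0.28), FCGR1A (0.24), CD68 (0.18), KLF1 (0.25), EPB42 (0.23) and HBB (0.02) did not pass. The adjusted p values in these sentences are from limma's camera, which gave 0.114, 0.144 and 0.174 for T cell, monocyte and erythroid markers.

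Between early (6 or 8 h) and late (24 h) arrays, LGALS1 was higher late and NOC3L, SLC39A14 and LBR were lower. The difference in log2 ratio was 1.10 for LGALS1 (SE 0.183, limma adjusted p = 0.0285), with means of 0.32 early and 1.42 late. It was -1.12 for NOC3L, a nucleolar protein of ribosome assembly (SE 0.185, adjusted p = 0.0285), -1.01 for the zinc transporter gene SLC39A14 (SE 0.186, adjusted p = 0.0357) and -0.96 for LBR, the lamin B receptor (SE 0.183, adjusted p = 0.0494). In all, 8 of 6798 rows differed in limma, 6 lower and 2 higher late, 4 of them features without a symbol, and 687 had an unadjusted p under 0.05 against 340 by chance. With each array centred on its median, 61 rows differed, 44 lower and 17 higher late. Genes that fill the rule and did not pass were SKI (0.84) and PDIA2 (0.85), ANTXR2 (0.84), GIT2 (-2.45), WASH5P (2.31) and CHRNB1 (-1.11). Left-out arrays moved the difference from 0.12 to 1.55 for ANTXR2, which had its 1 value above 0 (1.31) at 24 h against control siRNA, from 0.37 to 1.34 for PDIA2 and from 0.45 to 1.24 for SKI. GIT2, WASH5P and CHRNB1 each had 1 extreme array, with 4.63 at 8 h for GIT2 and 4.13 at 24 h for WASH5P against control siRNA, and -2.29 at 24 h against no siRNA for CHRNB1. The MYC difference, 0.41 (SE 0.188), did not pass (limma adjusted p = 0.467).

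The NF-kappaB targets had a median difference of -0.27 between late and early arrays (camera adjusted p = 4.88e-05 in limma, adjusted p = 0.645 with an estimated correlation and 0.564 with fry). The list stood at 0.32 and 0.21 on the early arrays and at -0.04 and 0.01 on the late ones, against control siRNA and no siRNA. Its lowest members, named after their values were seen, were NFKB1 (-0.57), which encodes a subunit of NF-kappaB itself, and the cytokine genes LTA (-0.55), IL10 (-0.55) and TNF (-0.54), none past the test (limma adjusted p of 0.247 to 0.306). The G1/S and DNA replication list (-0.17) was also lower late, by -0.14 in the pair of arrays against control siRNA and -0.25 in the pair against no siRNA. For the other lists that were lower late, the median difference in these pairs was -0.06 and -0.30 for textbook MYC-activated genes (-0.20 over both), -0.02 and -0.38 for translation factors (-0.23), -0.08 and -0.38 for aminoacyl-tRNA synthetases (-0.24), -0.05 and -0.19 for mitochondrial biogenesis (-0.18), -0.08 and -0.26 for glycolysis (-0.16), and -0.17 and -0.36 for housekeeping genes (-0.30). T cell markers were higher late (0.18), by 0.12 and 0.16. Of 165 genes in these 9 lists 0 passed limma by themselves, with 32 at an unadjusted p under 0.05. Camera's adjusted p in limma ran from 4.88e-05 (NF-kappaB targets) to 0.0419 (T cell markers), and with an estimated correlation the smallest adjusted p was 0.645. These list tests were added after the data were examined. With the arrays scaled to a common spread, 0 rows differed in limma (486 at an unadjusted p under 0.05). The calls of translation factors (-0.093), synthetases (-0.121), glycolysis (-0.117), mitochondrial biogenesis (-0.073) and T cell markers (0.138) were then lost. T cell markers also lost theirs with centred arrays (0.19, camera adjusted p = 0.0607). With an array left out, time was fitted without control kind and with a lone array on 1 side. Control kind therefore enters the differences given for these fits. Further calls were lost without single arrays. Without the 24 h array against control siRNA these were glycolysis (-0.23, adjusted p = 0.0557), mitochondrial biogenesis (-0.14, adjusted p = 0.0765) and T cell markers (0.10, adjusted p = 0.143). Without the 6 h array they were translation factors (-0.14, adjusted p = 0.272), synthetases (-0.15, adjusted p = 0.0539), mitochondrial biogenesis (-0.13, adjusted p = 0.328) and T cell markers (0.05, adjusted p = 0.418). Without the 24 h array against no siRNA they were translation factors (-0.02, adjusted p = 0.54), mitochondrial biogenesis (-0.13, adjusted p = 0.126), T cell markers (0.19, adjusted p = 0.0682) and housekeeping genes (-0.13, adjusted p = 0.151), and the difference of textbook MYC-activated genes was -0.11 and that of synthetases -0.11. Without the 6 h array glycolysis was at -0.08. For single rows, leaving out an array gave 0 rows without the 8 h and 3 without the 24 h array against control siRNA, and 1 without the 6 h and 2 without the 24 h array against no siRNA, with 267 rows at an unadjusted p under 0.05 where the count was 0.

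**Figure D3:**
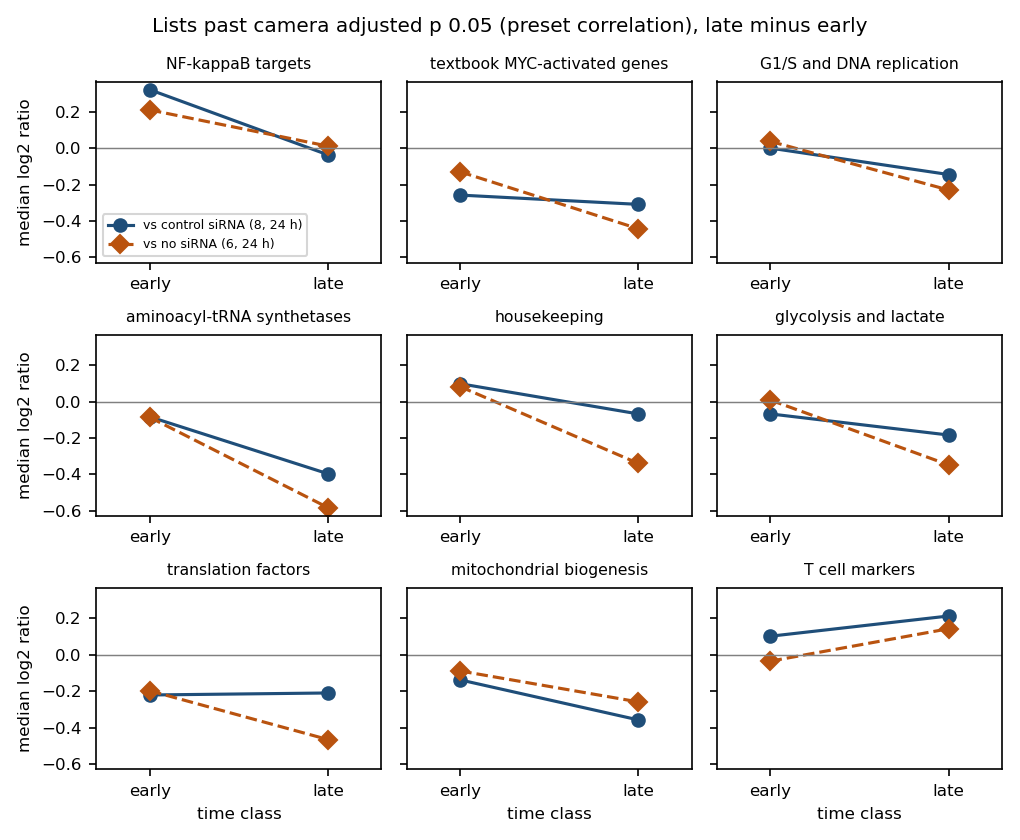
Median log2 ratio of MYC siRNA over control (y axis) on the early and late arrays (x axis) for the 9 lists past camera's adjusted p of 0.05 at the preset correlation, with 1 line per kind of control. The NF-kappaB list goes from 0.32 to -0.04 against control siRNA and from 0.21 to 0.01 against no siRNA.

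By the kind of control, USP54, TNFRSF1B and PLA2G6 had higher log2 ratios on the arrays against control siRNA than on those against no siRNA. The difference was 1.19 for the USP54 gene (SE 0.183, limma adjusted p = 0.0235), with means of 1.04 against control siRNA and -0.15 against no siRNA. TNFRSF1B, which encodes TNF receptor 2, differed by 1.11 (SE 0.183, adjusted p = 0.0258) and PLA2G6, a calcium-independent phospholipase, by 1.06 (SE 0.183, adjusted p = 0.0258). In all, 6 of 6798 rows differed in limma, 0 lower and 6 higher against control siRNA, and 3 of them were features without a symbol, while 685 had an unadjusted p under 0.05. With each array centred on its median 31 rows were lower and 58 higher, and over single features 16 and 41. SLC7A5, a large neutral amino acid transporter (-0.90), SELENOO (-1.23), RPAP2 (-0.83), ALYREF (-0.80) and TMEM134 (-0.80) led the other direction and did not pass, nor did GIT2 (2.17) and WASH5P (1.75). Left-out arrays moved SELENOO from -1.91 to -0.54, its lowest value being -1.53 at 24 h against control siRNA, and ALYREF from -1.19 to -0.40. Of 26 lists 0 passed camera (smallest adjusted p = 0.996, with 0 at an unadjusted p under 0.05), a test added after the data were examined. The kind of control goes with the experiment, so batch and control cannot be told apart. With arrays scaled to a common spread 0 rows differed in limma (565 at an unadjusted p under 0.05), and leaving out an array gave 26 rows without the 8 h and 19 without the 24 h array against control siRNA, and 1 without either array against no siRNA.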

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

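Tests of the MYC-activated list against random lists and abundant genes, of the interferon list on the arrays against control siRNA, of the NF-kappaB list within 1 pair of arrays, and all list tests by time were chosen after the result was seen.

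Single rows differed between the late and early arrays by limma's test of the difference. In log2 units, late minus early, NOC3L stood at -1.12, SLC39A14 at -1.01, LBR at -0.96 and LGALS1 at 1.10, and 4 features without a symbol at -1.17, -1.08, -0.97 and 1.39. Between arrays against control siRNA and no siRNA the difference was 1.19 for USP54, 1.11 for TNFRSF1B and 1.06 for PLA2G6, and 1.09, 1.05 and 0.99 for features without a symbol. None of these 14 rows passed with the arrays scaled to a common spread, where limma called 0 rows in either comparison (486 and 565 at an unadjusted p under 0.05). Of the lists, 9 differed between late and early by camera at the preset correlation; with an estimated correlation the smallest adjusted p among them was 0.645, and 0 of the 9 passed with fry. Their median differences were -0.27 (NF-kappaB targets), -0.20 (textbook MYC-activated genes), -0.17 (G1/S and DNA replication), -0.24 (aminoacyl-tRNA synthetases), -0.30 (housekeeping), -0.16 (glycolysis and lactate), -0.23 (translation factors), -0.18 (mitochondrial biogenesis) and 0.18 (T cell markers). Within the pair against control siRNA the difference was -0.016 for translation factors, -0.045 for mitochondrial biogenesis and -0.060 for the MYC-activated genes.

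The textbook MYC-activated list had a median below 0 on each of the 4 arrays (medians -0.26 and -0.31 against control siRNA and -0.13 and -0.44 against no siRNA, early array first), with a camera adjusted p of 9.18e-05 and adjusted p = 0.528 with an estimated correlation. A share of 1e-04 of 10000 random lists lay as low, the smallest that this number can give, but this restates the shift for which the list was picked, so bias of single features with no tie to gene function stays open. Bias growing with abundance would lower ribosomal protein and MHC class II genes as well, if these are abundant as was assumed. Their median was 0.015, above the list by 0.28 (permutation p = 1e-05, the smallest these draws can give). Abundance was not measured, the list was picked for being low, and the permutations take genes as independent. This bias is therefore not excluded. Bias of single genes in Cy5 against Cy3 cannot be told apart from a response, since 0 arrays had swapped dyes. A response of MYC-activated genes to lower MYC also stays open, as a hypothesis.

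The interferon list had a median above 0 on each array, with 10 of 28 members passing by themselves (camera adjusted p = 0.000419, and adjusted p = 0.528 with an estimated correlation). A response to any transfected siRNA would cancel where the control cells also held one. On those arrays the list's median was 0.318, with a share of 1e-04 of 10000 random lists as high, against 0.166 on the other arrays. Of 28 members, 20 were above 0 on both arrays against control siRNA. These arrays are part of the mean for which the list was picked. The share thus restates that shift in part and does not exclude such a response. A lean of features near background toward Cy5 stays open: 36 markers of other lineages had a median of 0.112 (share of random lists 0.0083), and the interferon list lay 0.099 above them, within the spread of permutations (p = 0.165). At 6 h the T cell, monocyte and erythroid medians were -0.035, 0.006 and -0.021 against 0.129 for the interferon list, and at 8 h 0.102, 0.085 and 0.13 against 0.314. At 24 h they were 0.213, 0.237 and 0.09 against 0.167 (control siRNA), and 0.143, 0.095 and 0.378 against 0.164 (no siRNA). The markers thus lay below the interferon list on the early arrays, but not throughout on the late ones. A response to this siRNA pool in particular, or to lower MYC, also stays open, since 1 pool was used.

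The NF-kappaB list had a lower median late than early in both pairs of arrays (camera adjusted p = 4.88e-05, and adjusted p = 0.645 with an estimated correlation). A wider spread of values on the 24 h array against no siRNA (SD 0.447) would leave the pair against control siRNA near 0. The difference there was -0.311, with a share of 1e-04 of 10000 random lists as low, so the drop was also present in a pair without that array. This pair entered the difference for which the list was picked, so the share restates that difference in part. The median difference was -0.182 in the other pair, and 24 of 32 members were lower late in both. Time after transfection, the difference named by the design, stays open as a biological explanation and was not tested apart from handling of the cells at each time.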

How the results depend on the processing

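The average over features complete on all 4 arrays was chosen after the data were examined. In the MYC siRNA comparison the 11 called lists and each called named gene kept their direction under every alternative run for them. For the genes this was largely set in advance. The lowest and highest were picked for 1 sign on all arrays, as 1066 of the 1073 changed rows had. Called lists kept their side of the threshold in 94 cases and lost it in 5 with camera at the preset correlation. With an estimated correlation and fry added they kept it in 100 cases and lost it in 21. Called genes kept it in 376 and lost it in 221. For the other 2 comparisons called genes kept it in 24 cases and lost it in 32, and lists by time in 46 and 17 (46 and 35 with an estimated correlation and fry added). A lone array on one side was assumed to vary like the others. For time and control kind, fits with an array left out held only the term tested. Their differences thus mix time with control kind.

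MYC ranged from -1.077 to -0.774 when arrays were left out. The count of 1073 changed rows ranged from 0 to 441 in that case, with 1796 to 2179 rows at an unadjusted p under 0.05 in limma. It was 1971 over single features, 1876 at an adjusted p of 0.10, 278 with a change of at least 0.5 and 1980 with time and control as terms. On pairs of arrays it was 0 against control siRNA (1622 at an unadjusted p under 0.05), 691 against no siRNA, 0 at 24 h (1804 unadjusted) and 4 at 6 and 8 h; fewer arrays entered there. The 11 lists became 0 with an estimated correlation (1 at an unadjusted p under 0.05). That setting has 3 residual degrees of freedom, so few calls can be made whatever the correlation. With fry, which does not compare a list with other genes, they became 7. Fry kept 6 of the 11, lost textbook MYC-activated genes (adjusted p = 0.0877), translation factors, synthetases and glycolysis (0.0886 each) and NF-kappaB targets (0.211), and gained the proteasome (0.0481). Glycolysis lost its call with scaled arrays (median -0.098). Lists that gained one were MHC class II (0.259), mature B cell (0.061) and monocyte markers (0.209) over single features, and MHC class II over complete features (0.192). Over single features a gene with several features counts several times, so these gains are not independent by gene. Where leaving out an array moved a list across the threshold, medians ranged from -0.407 to -0.180 (synthetases), -0.191 to -0.068 (glycolysis), -0.125 to -0.051 (G1/S), 0.063 to 0.184 (NF-kappaB), 0.093 to 0.238 (MHC class II) and 0.080 to 0.114 (T cell markers).

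The 8 rows by time became 61 with centred arrays, 0 with scaled arrays (486 unadjusted), 0 to 3 without an array, 74 over single features, 43 at an adjusted p of 0.10, 25 with a filter of 0.3, 5 with robust spread, 0 with time alone (437 unadjusted) and 26 over complete features. The 6 rows by control, 0 of them lower, became 89 (31 lower), 0 (565 unadjusted), 1 to 26, 57 (16 lower), 34 and 41 under the same settings from centring to the filter, 36 with rows on 3 arrays, 0 with control alone (454 unadjusted) and 37 over complete features. Limma's prior degrees of freedom, 17.5 as reported, were infinite after centring and 3.87 after scaling, and the cause of the changed counts was not tested.

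Signs turned for values that had not passed, and the cause was not tested. MYCN was 0.001 with scaled arrays and 0.084 over complete features. The immediate early list was -0.038 over single features and -0.027 with rows on 3 arrays, and housekeeping -0.008 over single features, where camera's direction turned. Without an array the ranges were -0.077 to 0.021 (MYCN), -0.063 to 0.082 (MYCL), -0.079 to 0.171 (MXD1), -0.020 to 0.043 (HBB), -2.282 to 0.053 (CHRNB1 by time), -0.151 to 4.496 (GIT2) and -0.608 to 4.113 (WASH5P, both by control). For lists they were -0.078 to 0.007 (ribosomal proteins), -0.116 to 0.039 (housekeeping) and -0.054 to 0.033 (MYC network). The MYC network median was also 0.009 with centred and 0.011 with scaled arrays and 0.066 over complete features, and that of p53 genes 0.006 over complete features, while camera's direction stayed. For immediate early (-0.107 to -0.028) and p53 genes (-0.078 to -0.006) the median stayed below 0 and camera's direction turned. Correlation between arrays stayed at 0.462 and 0.499. Signal over background is unknown here, so faint features could not be set apart.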

Other observations

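Families of genes with a shared symbol stem were tested as a hypothesis that members move together, set before the result was seen. Of 55 families with at least 8 measured genes, 1 passed limma's camera: the EIF genes of translation initiation, with 7 of 20 lower and 0 higher (median -0.21, adjusted p = 0.0421, and adjusted p = 0.963 with an estimated correlation). EIF2S1 and EIF2S2, subunits of the factor that brings the initiator tRNA, fell by 0.36 (SD 0.11) and 0.37 (SD 0.23), and EIF2B1, of its exchange factor, by 0.36 (SD 0.09; n = 4 each). EIF3H, of the EIF3 complex, averaged -0.31 ± 0.13. This family overlaps with the translation factor list and is not independent of it. Genes named CD for their surface antigens had 7 of 55 higher and 1 lower (median 0.10) and did not pass (adjusted p = 0.115).

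The lowest row of all was a feature without a symbol, 30623_1, at -1.19 ± 0.31 (SD, n = 4; limma adjusted p = 0.00946), below 0 on each array. It was followed by feature 29722_1 at -1.18 ± 0.34, whose values of -1.34, -0.69, -1.44 and -1.28 were least negative on the 24 h array against control siRNA, as those of MYC were.

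Turning the signs of some of the arrays, a pattern and its mirror taken as 1, gave 1 of 8 patterns with as many changed rows, namely the real one with 1073, and at most 0 in the others. With 8 patterns no share under 0.05 can be reached.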
